A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

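RNA of yeast cultures was measured in 24 libraries from 2 strains at 4 times. Per the labels' protocols, cultures of BY4741 (MATa his3Δ1 ura3Δ0 leu2Δ0 lys2Δ0, with a hygromycin-resistance and GFP construct on chromosome VI) and of the same strain with CNB1 replaced by KanMX grew in synthetic medium with ammonium chloride, RNA was extracted with acid phenol, and libraries were made after polyA enrichment. The submitters' processing notes name featureCounts, DESeq2 and genome build R64, with no versions. The aligner, the annotation release, the use of strand and the treatment of reads that match several places are not given in the sources used here.

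The authors deposited 1 table of raw counts per gene, whole numbers for 7126 genes and all 24 libraries, and 1 table of TPM (transcripts scaled to a fixed total) for 6744 genes. The deposited TPM values were used only for alternatives. The 382 genes absent from the TPM table had a total count over the 24 libraries of at most 9, and every gene present had at least 10. All columns were used, matched to samples by their names and titles, which also give the replicate number. A symbol came from the count table for 5110 genes and from the reference by locus tag for 240, and 1776 have none. Every line names a gene. Before averaging, a chi-square test of replicates over genes with at least 20 counts gave 4.61 to 324 per degree of freedom. No pair was thus within sampling noise. In cnb1Δ, replicates 1 and 3 gave 5.39 (0 h) and 4.61 (12 h) and pairs with replicate 2 gave 32.0 to 55.9. These replicates may not be equally independent.

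Genes were filtered with edgeR's filterByExpr by group, which left 6253. Libraries were scaled by TMM (trimmed mean of M-values) and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) in 1 model of 8 group means over all 24 libraries, with 16 residual degrees of freedom, so that the groups share 1 estimate of the spread. The 16 comparisons were each time against 0 h within a strain, the difference of these changes between strains (the interaction, positive where the cnb1Δ response lies above that of WT), cnb1Δ against WT at each time, and 72 h against 12 h within each strain and between strains. Adjusted p-values are Benjamini-Hochberg values within a comparison, two-sided, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with an approximate SE, the absolute log2 fold change divided by the square root of its F statistic. CPM values (counts scaled to a fixed library total) are TMM-scaled group means ± SD, and log2 CPM values used a prior count of 2.

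Gene lists were fixed before the data were examined, 35 in number, of which 34 had a tested member: no member of the list of mitochondrially encoded RNAs was tested. The lists were Crz1 targets, calcium handling and calcineurin, cell wall integrity, general stress, osmotic response, heat shock chaperones, unfolded protein response, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I, translation factors, G1/S, histones, S phase genes linked to Hcm1, the G2/M CLB2 cluster, M/G1 daughter genes, the phosphate, iron and zinc regulons, ergosterol synthesis, mitochondrial respiration, the TCA and glyoxylate cycle, glycolysis, hexose transporters, amino acid synthesis, nitrogen catabolite genes, methionine and sulfate, the proteasome, the vacuolar H+-ATPase, pheromone response, and MATa-specific, MATalpha-specific, meiosis and stationary phase genes as signs of other cell types or states. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 against the other genes, with adjustment over all 544 list tests, and again with an estimated correlation and with fry. Member counts are also given adjusted over the list alone.

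Named genes followed a rule set before the data were examined. Only genes with a standard name, a group mean of at least 20 CPM in 1 compared group, an adjusted p under 0.05 and no overlap between the compared libraries were ranked by log2 fold change. The text could take the 10 highest and 10 lowest for WT at 12 h against 0 h, for the interactions at 12 h and 72 h and for the strains at 0 h, and 5 each for every other comparison. CNB1 and the deleted marker genes stood apart from this ranking. Up to 4 called members with the largest change could be named for each list, and any member of the Crz1 and calcium lists. In a comparison of 3 libraries with 3, chance leaves a gene without overlap in 10% of cases.

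The replicate numbers in the titles were checked for pairing by the correlation of same-numbered libraries' deviations from their group means. They paired the libraries where all 3 correlations were over 0.1, which held for WT at 12 h against 0 h (0.228 to 0.396) and for cnb1Δ against WT at 0 h (0.193 to 0.229), 48 h (0.162 to 0.569) and 72 h (0.314 to 0.689), and for no other comparison. The interactions at 48 h and 72 h are thus differences of paired strain differences, though by this rule numbers do not pair those times with 0 h. The pairing comes from these values, since the labels do not say what a number shares. The fit without a block was set as the main one before the data were examined.

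Alternatives were RLE size factors, total count scaling, no filter, a mean of at least 10 CPM, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean of at least 1 TPM and on all genes, fits of the compared groups alone, the replicate number as a block over all libraries or within strain, and leaving out each library in turn. Added after the data were examined were the 48 h and 72 h groups without their replicate 1 libraries, the replicate number as a block within each time for comparisons of the strains at 0, 48 and 72 h and their interactions, and list tests leaving out each library in turn. The steps were tested on simulated counts of the 6253 genes with known changes. In the simulated interaction at 12 h, 11.9% of 1.5-fold, 64.2% of 2-fold and 98.5% of 4-fold changes were called, with 0.116% of unchanged genes, and in the simulated change in cnb1Δ at 12 h 62.7%, 86.6% and 98.5%, with 0.249%.

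Positions are of the annotated gene in the R64 reference, in which 6048 of the 7126 genes were found by locus tag. Coding length and GC content were known for 5730 of the tested genes (91.6%), and 96.5% of those lengths are multiples of 3. Genes with a copy of at least 90% identity over at least 50% of their length were found with blastn 2.17.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.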

Results

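RNA was sequenced from cultures of the budding yeast Saccharomyces cerevisiae, strain BY4741, a haploid laboratory strain of mating type a. A wild type (WT) and a strain that lacks CNB1 (cnb1Δ) were compared. CNB1 encodes the regulatory subunit of calcineurin, a protein phosphatase switched on by calcium and calmodulin whose targets include the transcription factor Crz1. Each strain was sampled at 0 h, before the addition of 200 mM CaCl2, and after 12, 48 and 72 h of growth in it, with dilution every 12 h to hold the cultures in logarithmic growth. No culture without CaCl2 was sampled at 12, 48 or 72 h, so a change from 0 h may come from CaCl2 or from time in culture and repeated dilution, which these samples cannot separate. The question put by the design is which changes in gene expression under long calcium chloride stress need calcineurin. The 8 groups held 3 libraries each, 24 in all, with total counts of 18843220 to 22250806 per library, and 6253 of the 7126 genes counted passed the filter on low counts. Changes are given as log2 fold changes ± SE with n = 3 libraries in each group. The p-values pool a gene's spread over all 24 samples, which the labels call triplicate time courses. Genes ranked by size of change had no overlap between the 3 libraries of one group and the 3 of the other, and words such as highest or furthest refer to the genes that pass that rule. For a difference between responses the rule compares each library's log2 value minus the 0 h mean of its strain.

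The first principal component of the normalised values held 49.5% of the variance and parted the 0 h libraries from those in CaCl2, and the second held 16.7%. The replicate 1 libraries of the 48 h and 72 h groups deviated from their group means together in both strains, with correlations across genes of 0.569 to 0.695 (6 pairs). In these 4 libraries the 30 measured genes of the general stress response list were on average higher, relative to WT at 0 h, than in the other libraries of their groups. The mean log2 differences were 1.57 against −0.69 in WT at 48 h, 0.90 against 0.20 in WT at 72 h, 0.78 against −0.04 in cnb1Δ at 48 h and 1.20 against 0.28 in cnb1Δ at 72 h.

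**Figure D1:**
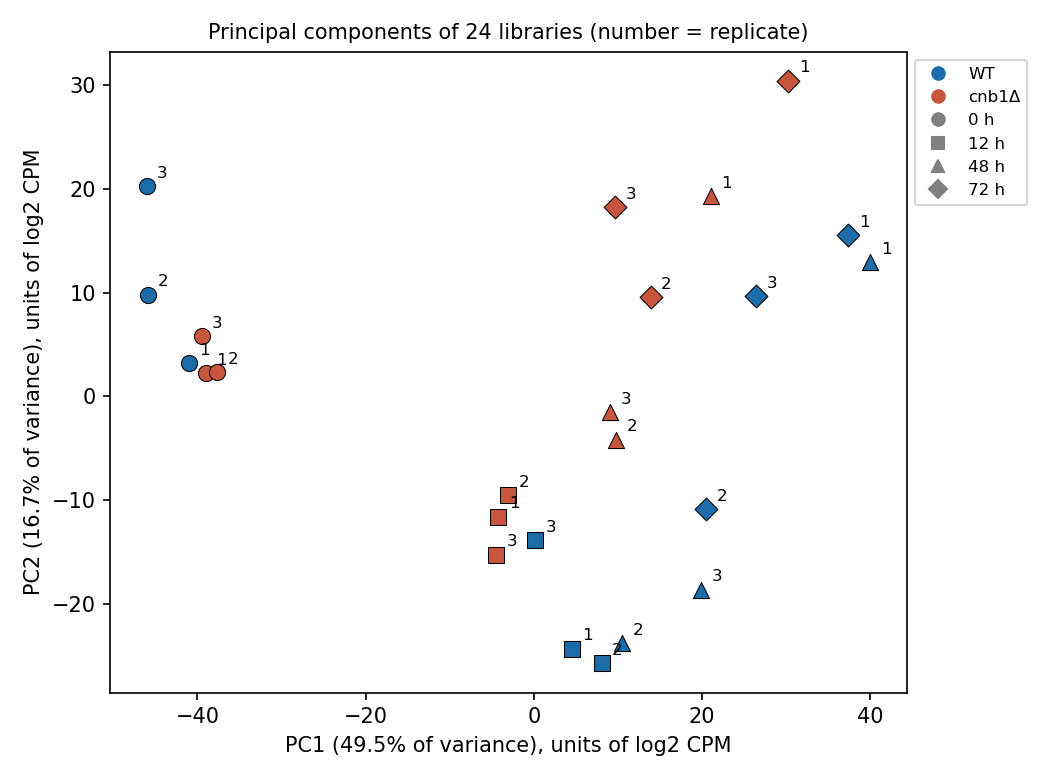
Principal components 1 and 2 of log2 CPM (counts scaled to a fixed library total) over all 24 libraries, with 49.5% and 16.7% of the variance on the axes. Each point is 1 library, coloured by strain, shaped by time and numbered by replicate, and the 0 h libraries of both strains lie apart from those in CaCl2.

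CNB1 (YKL190W, chromosome XI, 82947 to 83550, genome build R64) was counted 996 to 1221 times in the WT libraries at 0 h, 1478 to 1951 times at 12 h, 1913 to 3320 times at 48 h and 2487 to 2699 times at 72 h. In the cnb1Δ libraries its counts were 11, 9 and 0 at 0 h, 10, 6 and 11 at 12 h, 14, 23 and 8 at 48 h and 7, 13 and 14 at 72 h, so each library matched its strain label. The count of 0 allows up to 3 counts and covers counting error only. URA3 and LEU2, which are deleted in this background, had 0 counts in all 24 libraries, and LYS2 had 0 counts in all but replicate 1 of cnb1Δ at 12 h, which had 1. HIS3, of which the his3Δ1 allele removes only a part, had 455 to 2094 counts and checks nothing.

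In WT cells after 12 h in CaCl2, genes of iron uptake were higher than at 0 h and those of mating, respiration and amino acid synthesis lower. FIT1 (YDR534C, chromosome IV, 1503314 to 1504900), a cell wall mannoprotein that retains iron siderophores, rose 70.9-fold (6.15 ± 0.34, edgeR adjusted p = 1.4e-10), from 19.3 ± 2.51 to 1367 ± 88.9 CPM (SD, n = 3). FUS1 (YCL027W, chromosome III, 71803 to 73341), which acts in cell fusion during mating, fell by 4.80 ± 0.42 (edgeR adjusted p = 1.09e-07), or by 2.98 in limma on log2(TPM + 1). Of 6253 genes, 1541 rose and 1403 fell.

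Of the 16 measured genes of the iron regulon, which is switched on when cells sense low iron, 11 rose and 0 fell (12 and 1 adjusted over the list alone). Their median was 1.55 (camera adjusted p = 1.17e-05, 0.581 with estimated correlation). Next to FIT1, the largest rises of the list were FIT3 (4.91 ± 0.41), the ferric reductase gene FRE2 (3.29 ± 0.35) and the siderophore transporter gene ARN1 (3.08 ± 0.38). LSO1, which is induced in low iron, was a further gene of the largest rises (5.29 ± 1.02). The others were HES1, which encodes an oxysterol-binding protein (5.11 ± 0.61), YSR3, for a phosphatase of sphingoid base phosphates (4.39 ± 0.41), CSS1 (3.74 ± 0.60), PBI1 (3.48 ± 0.60), the hexose transporter gene HXT5 (3.17 ± 0.98) and YHK8 (3.12 ± 0.48). The genes that fell furthest were FUS1, FMP48 (−4.79 ± 0.51), MFA1 (−4.54 ± 0.29) and AGA2 (−4.13 ± 0.20), for a-factor and a subunit of a-agglutinin. They were followed by the alpha-factor protease gene BAR1 (−3.24 ± 0.31), AGA1 (−3.24 ± 0.18), the mitochondrial pyruvate carrier gene MPC3 (−3.03 ± 0.71), GPD1 (−3.01 ± 0.27), for a glycerol synthesis enzyme, CWP1 (−2.99 ± 0.28), for a cell wall mannoprotein, and SER3 (−2.98 ± 0.35). SER3 is overlapped on its own strand by SRG1, so its reads may not be its own alone.

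All 6 measured MATa-specific genes fell (median −2.90, camera adjusted p = 5.58e-07, 0.103 with estimated correlation; 0 and 6 adjusted over the list alone), among them MFA2 (−2.56 ± 0.23). Of 14 pheromone response genes, 0 rose and 11 fell (0 and 13 adjusted over the list alone), with FIG1 (−4.48 ± 0.52) and SST2 (−2.82 ± 0.17) next to FUS1 and AGA1 (camera adjusted p = 2.05e-07, 0.135 with estimated correlation). FIG1 stood at −1.58 in limma on log2(TPM + 1) without a filter, and in the other limma settings it did not pass the filter. Of 31 nuclear genes of mitochondrial respiration, 0 rose and 27 fell (0 and 27 adjusted over the list alone), led by CYC1, which encodes cytochrome c (−2.83 ± 0.55), SDH2 (−2.57 ± 0.12), QCR10 (−2.47 ± 0.21) and RIP1 (−2.34 ± 0.23). The respiration median was −1.18 (camera adjusted p = 1.77e-12, 0.26 with estimated correlation). In the TCA and glyoxylate cycle 1 rose and 8 fell (1 and 9 adjusted over the list alone) of 16, with ACO1 at −1.11 ± 0.19 (camera adjusted p = 0.0134, 0.357 with estimated correlation). In glycolysis 1 rose and 13 fell (2 and 13 adjusted over the list alone) of 16, among them FBA1 (−1.41 ± 0.22) and TDH2 (−1.36 ± 0.25; camera adjusted p = 0.000519, 0.695 with estimated correlation). Amino acid synthesis lost 26 of 29 genes and gained 0 (0 and 26 adjusted over the list alone; camera adjusted p = 2.7e-08, 0.57 with estimated correlation). The arginine genes ARG1 (−2.75 ± 0.37) and ARG3 (−2.09 ± 0.39) and LYS1 (−2.05 ± 0.28) were furthest down. In the methionine and sulfate list 2 rose and 10 fell (2 and 11 adjusted over the list alone) of 16, with MET5 (−1.96 ± 0.28) and MET6 (−1.83 ± 0.34; camera adjusted p = 0.00173, 0.57 with estimated correlation). Of 15 phosphate regulon genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone), among them the phosphatase genes PHO5 (−1.63 ± 0.17) and PHO8 (−1.53 ± 0.23; camera adjusted p = 0.0067, 0.734 with estimated correlation).

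Ribosome biogenesis, histone and ergosterol genes rose at 12 h. Of 109 ribosome biogenesis genes, 87 rose and 1 fell (90 and 1 adjusted over the list alone), among them RRP36 (0.96 ± 0.13) and NMD3 (0.94 ± 0.15). Their median was 0.59 (camera adjusted p = 1.43e-13, 0.714 with estimated correlation). The 138 genes of the cytosolic ribosomal protein list were not called as a set (camera adjusted p = 0.304). Of these, 9 rose and 17 fell (2 and 7 adjusted over the list alone), with a median of −0.10 that turned to 0.07 under total count scaling. One of its called members, RPP1 (0.81 ± 0.15), was caught by its name and encodes a subunit of RNase P. Histone genes rose, 7 of 8 (7 and 0 adjusted over the list alone), among them HHT1 (0.96 ± 0.13) and HHF2 (0.62 ± 0.15; camera adjusted p = 0.00868, 0.652 with estimated correlation). In ergosterol synthesis 12 rose and 1 fell (12 and 1 adjusted over the list alone) of 23, with ERG3 (1.45 ± 0.13) and ERG27 (1.23 ± 0.11; camera adjusted p = 0.000689, 0.685 with estimated correlation).

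Of the 16 Crz1 targets, genes activated by the transcription factor that calcineurin acts on, 5 rose and 0 fell (4 and 0 adjusted over the list alone). GSC2 (YGR032W, chromosome VII, 548264 to 553951), which encodes a subunit of 1,3-beta-glucan synthase, rose by 2.85 ± 0.31, edgeR adjusted p = 1.2e-06, from 112 ± 6.45 to 808 ± 207 CPM. The wall genes CRH1 (1.16 ± 0.15), CHS1 (0.63 ± 0.14) and NCW2 (0.63 ± 0.18) rose less, and the list median was 0.35 (camera adjusted p = 0.0492, 0.758 with estimated correlation). The vacuolar calcium pump gene PMC1 rose by 0.44 ± 0.18 (edgeR adjusted p = 0.0461). That call ended with RLE size factors (edgeR adjusted p = 0.0503), with a minimum mean of 10 CPM (0.0551), without WT replicate 2 (0.15) or 3 (0.073) at 0 h and without WT replicate 1 (0.194) or 3 (0.148) at 12 h. Among 12 genes of calcium handling and calcineurin, 0 rose and 3 fell (0 and 3 adjusted over the list alone), and both catalytic subunit genes of calcineurin were lower, CNA1 (−0.74 ± 0.12) and CMP2 (−0.70 ± 0.12). The list as a whole was not called (camera adjusted p = 0.632). CRZ1 itself stood at 0.02 ± 0.09 (edgeR adjusted p = 0.837). In the osmotic response list 0 rose and 6 fell (0 and 6 adjusted over the list alone) of 11, with GRE2 (−1.29 ± 0.28) and GPP1 (−0.88 ± 0.18) next to GPD1. The osmotic list was called (camera adjusted p = 0.0457, 0.0549 with the replicate number as a block, and 0.734 with an estimated correlation). Of 15 heat shock chaperone genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone), among them SSA2 (−0.78 ± 0.14) and AHA1 (−0.72 ± 0.11). That list was called too (camera adjusted p = 0.0442, 0.0528 with the replicate number as a block, and 0.758 with an estimated correlation). Of 30 general stress genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone), with CTT1, for cytosolic catalase, at −2.75 ± 0.26 (camera adjusted p = 0.131). Total count scaling ended the list calls of Crz1 targets (camera adjusted p = 0.0505) and heat shock chaperones (0.0501). The call of Crz1 targets also ended without WT replicate 1 (0.0551) or 2 (0.0669) at 0 h or 1 (0.105) or 3 (0.134) at 12 h (camera adjusted p). That of the chaperones ended without WT replicate 3 at 0 h (0.0692) or 2 (0.0721) or 3 (0.0524) at 12 h, and that of the osmotic list without WT replicate 3 at 0 h (0.0504) or 2 at 12 h (0.0999). No list call of any comparison held with an estimated correlation. Scaling to total counts set the median of all genes at 0.18 at 12 h, 0.38 at 48 h and 0.38 at 72 h in WT and at 0.22, 0.29 and 0.34 in cnb1Δ. It was 0.11 between the strains at 12 h and, from 12 h to 72 h, 0.16 in WT and 0.10 in cnb1Δ, so all changes are relative to the middle of the genes tested. With that scaling the share of called genes that rose was 70.1% instead of 52.3% at 12 h in WT, and 70.7% to 71.6% in limma on TPM values.

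**Figure D2:**
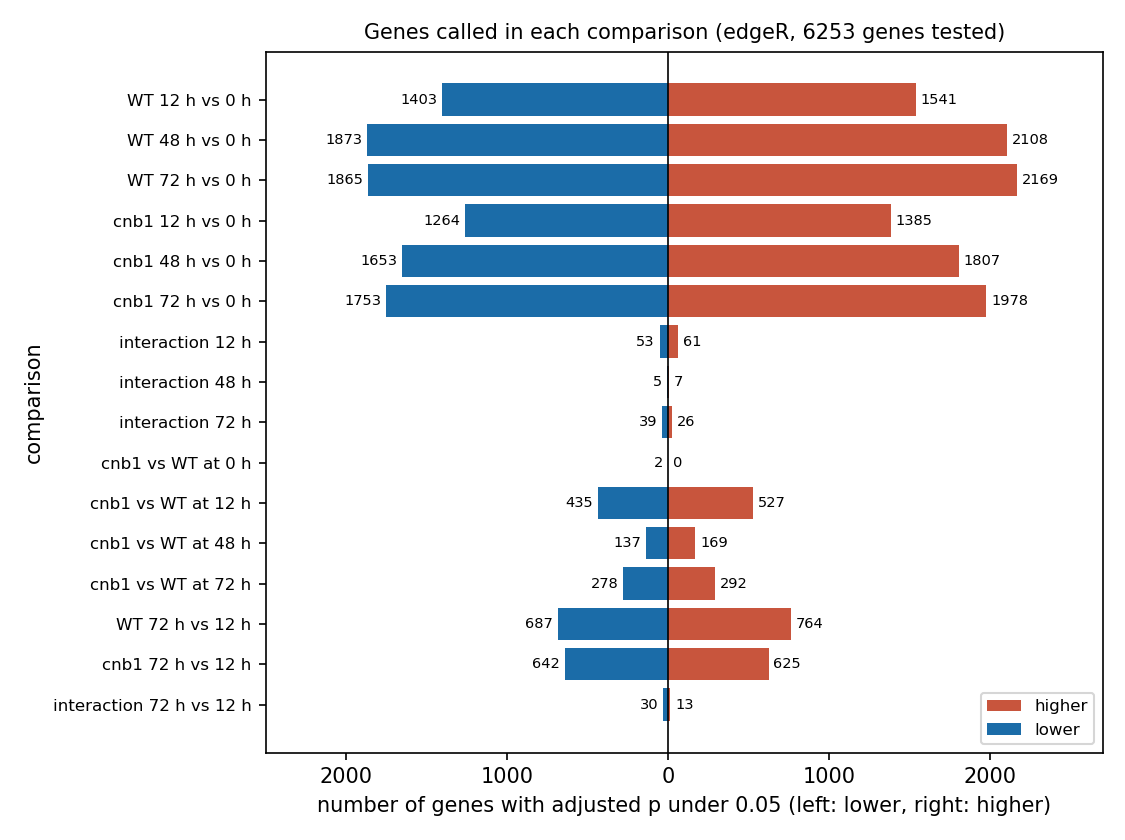
Number of genes called (edgeR adjusted p under 0.05) in each of the 16 comparisons, of 6253 tested. Bars to either side give genes higher and lower, from 2 genes between the strains at 0 h to 4034 in WT after 72 h.

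After 48 and 72 h in CaCl2 iron genes again led the rise in WT and mating genes were among the furthest down. At 48 h 2108 genes rose and 1873 fell. At 72 h 2169 rose and 1865 fell. LSO1 (7.68 ± 1.10 at 48 h and 7.87 ± 1.11 at 72 h) and FIT1 (6.65 ± 0.34 and 6.75 ± 0.35) stood highest. FMP48 (−6.88 ± 0.57 and −5.89 ± 0.54) fell furthest. Also among the 5 lowest were IMD2 (−4.53 ± 0.73 and −5.39 ± 0.77), which encodes IMP dehydrogenase, FUS1 (−4.50 ± 0.40 and −4.78 ± 0.41, or −2.84 and −2.95 in limma on log2(TPM + 1)) and MFA1 (−4.45 ± 0.29 and −4.10 ± 0.28), with AGA2 (−4.07 ± 0.20) at 48 h and LEU1 (−4.52 ± 0.45), for a leucine synthesis enzyme, at 72 h. HXT5 rose by 5.75 ± 1.04 at 48 h and RTA1 (YGR213C, chromosome VII, 918512 to 919465) by 5.63 ± 0.56 at 72 h. The small heat shock protein gene HSP26 (5.36 ± 1.31 and 5.53 ± 1.32) and PAU5 (5.29 ± 1.55 and 5.57 ± 1.56) rose too. Without WT replicate 1 at 48 h the 48 h changes were 3.62 for HXT5, 5.97 for LSO1, 2.32 for HSP26 and 2.46 for PAU5, and the calls of the last 2 ended (edgeR adjusted p = 0.0578 and 0.158).

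Of 16 iron regulon genes 14 rose and 0 fell (14 and 0 adjusted over the list alone) at 72 h, with a median of 2.30 (camera adjusted p = 1.64e-05, 0.581 with estimated correlation). At 48 h 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 2.34 (camera adjusted p = 4.52e-06, 0.57 with estimated correlation), which was 1.47 without WT replicate 1 at 48 h. In the phosphate regulon 2 rose and 12 fell (2 and 12 adjusted over the list alone) of 15 at 48 h (camera adjusted p = 0.00132, 0.667 with estimated correlation). At 72 h 1 rose and 13 fell (1 and 13 adjusted over the list alone) (camera adjusted p = 3.59e-05, 0.564 with estimated correlation), and the acid phosphatase genes PHO11 (−3.87 ± 0.43) and PHO12 (−3.40 ± 0.32) and PHM6 (−3.09 ± 0.34) were lowest. PHO11 (chromosome I, 225460 to 226863) and PHO12 (chromosome VIII, 552099 to 553502) are 99.7% identical, so their values are uncertain one by one. The 6 MATa-specific genes fell at both times (medians −3.56 and −3.72; camera adjusted p = 9.44e-06, 0.135 with estimated correlation at 72 h). At 72 h 14 of 14 pheromone response genes fell (0 and 14 adjusted over the list alone; camera adjusted p = 1.33e-06, 0.176 with estimated correlation). Respiration had 27 of 31 genes down at 48 h (camera adjusted p = 6.56e-11, 0.335 with estimated correlation). At 72 h 26 were down (camera adjusted p = 3.26e-10, 0.357 with estimated correlation), with CYC1 at −4.65 ± 0.62. Amino acid synthesis had 25 of 29 down (0 and 25 adjusted over the list alone; camera adjusted p = 3.99e-08, 0.57 with estimated correlation). Ribosome biogenesis had 85 of 109 up (camera adjusted p = 7.01e-09, 0.802 with estimated correlation), with SSF1 at 1.21 ± 0.13.

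Of the 16 Crz1 targets, 10 rose and 0 fell (10 and 0 adjusted over the list alone) at 72 h, with a median of 0.73 (camera adjusted p = 0.0215, 0.7 with estimated correlation). That call ended without WT replicate 3 at 72 h (camera adjusted p = 0.0621). At 48 h 5 rose and 0 fell (5 and 0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.153). GSC2 rose by 2.97 ± 0.31 at 48 h and 3.11 ± 0.32 at 72 h. CMK2 (YOL016C, chromosome XV, 294777 to 296120), a calmodulin-dependent protein kinase gene, rose by 2.10 ± 0.32 at 72 h, NCW2 by 1.55 ± 0.18 and GYP7 by 1.10 ± 0.19. In the calcium list CMK1 rose at 72 h (1.19 ± 0.25), and CNA1 (−1.25 ± 0.12) and CMP2 (−1.10 ± 0.12) fell, without a call for the list (camera adjusted p = 0.497). The general stress list split at 72 h into 11 genes that rose and 5 that fell of 30 (11 and 5 adjusted over the list alone; camera adjusted p = 0.773). Under total count scaling 73.8% of the called genes rose at 48 h and 71.9% at 72 h, and in limma on TPM values 72.4% to 72.8% and 69.9% to 70.8%, instead of 53.0% and 53.8%.

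In cnb1Δ cells iron genes rose and mating and respiration genes fell at 12 h. FIT1 (3.80 ± 0.30), FIT3 (3.26 ± 0.38), the ferric reductase gene FRE5 (3.18 ± 0.33), HPF1 (3.12 ± 0.52) and HMX1, for heme oxygenase (2.77 ± 0.85), rose furthest. FMP48 (−3.96 ± 0.49), AGA2 (−2.98 ± 0.19), MPC3 (−2.73 ± 0.70), GPD1 (−2.60 ± 0.27) and AGA1 (−2.48 ± 0.17) fell furthest. Of the genes tested 1385 rose and 1264 fell. Iron regulon genes rose, 14 of 16 (15 and 0 adjusted over the list alone; camera adjusted p = 1.42e-08, 0.43 with estimated correlation). MATa-specific genes fell, 6 of 6 (0 and 6 adjusted over the list alone), with a median of −1.37 (camera adjusted p = 0.000102, 0.184 with estimated correlation). Of the respiration genes 24 of 31 fell (1 and 27 adjusted over the list alone; camera adjusted p = 4.28e-10, 0.357 with estimated correlation), with SDH2 (−2.35 ± 0.12) and SDH1 (−2.11 ± 0.15) lowest. The G1/S list, genes switched on as cells enter the cycle, rose in 14 of 22 members and fell in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 0.000129, 0.581 with estimated correlation). PCL1 (1.55 ± 0.12) and POL1 (1.11 ± 0.12) were among those that rose. Of 16 Crz1 targets 2 rose and 1 fell (2 and 0 adjusted over the list alone), while the list was not called (camera adjusted p = 0.808). GSC2 stood at −0.11 ± 0.29 (edgeR adjusted p = 0.782) and CRH1 rose by 0.83 ± 0.15.

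At 48 and 72 h in cnb1Δ 1807 and 1978 genes rose and 1653 and 1753 fell. FIT1 (6.12 ± 0.34 and 6.45 ± 0.34), LSO1 (5.74 and 6.52) and FIT3 (4.50 ± 0.41 and 4.85 ± 0.41) were the 3 highest at both times. FRE2 (3.94 ± 0.35) was next at 48 h and HMX1 (4.26 ± 0.89) was among the 5 highest at 72 h. FMP48 (−5.76 ± 0.54 and −5.51 ± 0.53), LEU1 (−3.20 ± 0.42 and −3.76 ± 0.43) and AIM17 (−3.42 ± 0.38 and −3.27 ± 0.38) were among the 5 lowest at both times. AGA2 (−3.17 ± 0.19) and MGA1 (−3.15 ± 0.37) were so at 48 h and IMD2 (−4.26 ± 0.72) and AGA1 (−3.32 ± 0.18) at 72 h. In the iron regulon 15 rose and 0 fell (15 and 0 adjusted over the list alone) of 16 at 72 h (camera adjusted p = 4.15e-08, 0.453 with estimated correlation). Respiration had 25 of 31 genes down (0 and 26 adjusted over the list alone; camera adjusted p = 3.75e-10, 0.357 with estimated correlation). The 6 MATa-specific genes all fell (median −2.04, camera adjusted p = 0.000142, 0.185 with estimated correlation). In the phosphate regulon 10 of 15 genes fell with 2 up (2 and 10 adjusted over the list alone; camera adjusted p = 0.0107, 0.754 with estimated correlation). Ribosome biogenesis had 74 of 109 genes up (74 and 7 adjusted over the list alone; camera adjusted p = 4.96e-07, 0.849 with estimated correlation). The ribosomal protein list had 14 genes up and 51 down at 72 h (13 and 49 adjusted over the list alone). Its median of −0.18 turned to 0.10 under total count scaling (camera adjusted p = 0.00724, 0.978 with estimated correlation). Without replicate 1 of cnb1Δ at 72 h, 21 were up and 34 down with a median of −0.05, and the list call ended (camera adjusted p = 0.457), as it did under total count scaling (0.0916), without the late replicate 1 libraries (0.141) and by fry (0.306). Without replicate 3 the median was −0.29. Crz1 targets were not called at either time (camera adjusted p = 0.614 at 48 h; camera adjusted p = 0.532 at 72 h). At 72 h 2 rose and 5 fell (0 and 5 adjusted over the list alone), with ENA1 (−0.78 ± 0.17) and the phosphate cotransporter gene PHO89 (−1.76 ± 0.47) down. ENA1 is 98.7% identical to ENA2, so its value is uncertain, and it was −0.49 under total count scaling and −0.44 to −0.50 in limma on TPM values. CRZ1 rose in cnb1Δ (0.39 ± 0.09, 0.42 ± 0.09 and 0.50 ± 0.09 at 12, 48 and 72 h), but its response was not called as different from WT (edgeR adjusted p = 0.18, 0.345 and 0.162). Its rise was 0.59, 0.66 and 0.80 under total count scaling and 0.58, 0.63 and 0.76 in limma on log2(TPM + 0.1). With total count scaling 77.6%, 73.0% and 73.8% of called genes rose at 12, 48 and 72 h in cnb1Δ instead of 52.3%, 52.2% and 53.0%, and in limma on TPM values 76.4% to 77.5%, 69.8% to 71.3% and 71.5% to 72.9%.

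Across all 6253 genes the responses of the strains were correlated, with Pearson's r of 0.776 at 12 h, 0.858 at 48 h and 0.834 at 72 h. These are correlations across genes, which are not independent replicates, and each strain has its own 0 h libraries. Of 1927 genes called in both strains at 12 h, 1916 changed in the same direction, 1004 higher and 912 lower, where independent lists would share 341 and 284. At 48 h it was 3069 of 3073 and at 72 h 3198 of 3205.

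The difference between the strains' responses at 12 h was tested as an interaction. The responses of 114 genes differed, 61 above the WT response in cnb1Δ and 53 below it. GSC2 is an example of those below (−2.96 ± 0.42, edgeR adjusted p = 0.00101): it went from 112 ± 6.45 to 808 ± 207 CPM in WT and from 91.2 ± 9.72 to 84.3 ± 10.3 CPM in cnb1Δ. CWP1 (YKL096W, chromosome XI, 261132 to 261851) is one of those above (2.51 ± 0.37, edgeR adjusted p = 0.00117): it went from 608 ± 22.6 to 76.7 ± 30.8 CPM in WT and from 636 ± 60.2 to 457 ± 138 CPM in cnb1Δ. Of the 53 genes below, 33 rose in WT and were not called in cnb1Δ, 8 rose in WT and fell in cnb1Δ, 7 rose in both and 5 fell in cnb1Δ and were not called in WT. Of the 61 above, 29 fell in WT and were not called in cnb1Δ, 19 rose in cnb1Δ and were not called in WT, 11 fell in both and 2 fell in WT and rose in cnb1Δ.

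Furthest below were YSR3 (chromosome XI, 534067 to 535281; −4.44 ± 0.56), PBI1 (−4.40 ± 0.83), HES1 (chromosome XV, 781994 to 783298; −4.27 ± 0.82), FHN1 (−3.25 ± 0.63) and YHK8 (−3.21 ± 0.65), then GSC2, FIT1 (−2.35 ± 0.39) and IZH4 (−2.31 ± 0.42). FIT1 thus rose in both strains and further in WT, while YSR3 changed by 4.39 ± 0.41 in WT and stood at −0.05 ± 0.40 in cnb1Δ (edgeR adjusted p = 0.927). Furthest above were FUS1 (2.86 ± 0.53), MFA1 (chromosome IV, 1385176 to 1385286; 2.60 ± 0.36), CWP1, MDG1 (1.70 ± 0.27), HO, for the mating-type endonuclease (1.59 ± 0.21), and the arginase gene CAR1 (1.37 ± 0.25). In limma on log2(TPM + 1) FUS1 was at 1.59, below MFA1 at 2.61, and it did not pass a minimum mean of 10 CPM. MFA1 fell from 401 ± 75 to 17.2 ± 4.3 CPM in WT and from 299 ± 16.1 to 77.6 ± 4.26 in cnb1Δ. The calls of 6 further genes of the rule, MFA2, BAR1, NFG1, PHD1, MNC1 and SCM4, each ended when 1 of the libraries was left out. Their values stand in the closing section.

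Among the lists at 12 h, ergosterol synthesis had the lowest camera p. The cnb1Δ response was below that of WT in 7 of 23 genes and above in 0 (0 and 15 adjusted over the list alone). The ergosterol median was −0.68 (camera adjusted p = 7.2e-15, 0.184 with estimated correlation), and ERG28 (−1.52 ± 0.23, edgeR adjusted p = 0.00131) differed most, followed by ERG27 (edgeR adjusted p = 0.00131). Of 22 G1/S genes 6 were above and 0 below (12 and 0 adjusted over the list alone; median 0.53, camera adjusted p = 2.01e-11, 0.213 with estimated correlation), among them RFA1 (0.90 ± 0.13). Of 12 genes of the G2/M CLB2 cluster 2 were below and 0 above (0 and 7 adjusted over the list alone; median −0.51, camera adjusted p = 3.48e-07, 0.386 with estimated correlation). Heat shock chaperones were above in 2 of 15, STI1 (1.31 ± 0.27) and AHA1 (0.92 ± 0.16), and below in 0 (11 and 0 adjusted over the list alone; median 0.62, camera adjusted p = 3.81e-10, 0.171 with estimated correlation). In limma on TPM values the call of STI1 ended in all 3 settings (adjusted p = 0.0592 to 0.0719) and that of AHA1 without a filter (0.0551). MATa-specific genes were above in 4 of 6 (6 and 0 adjusted over the list alone; median 1.30, camera adjusted p = 8.96e-08, 0.0855 with estimated correlation). Of 14 pheromone response genes 2 were above, FUS1 and SST2 (1.22 ± 0.22), and 0 below (3 and 0 adjusted over the list alone; camera adjusted p = 0.000649, 0.386 with estimated correlation). Crz1 targets had 1 called member, GSC2, below (0 and 3 adjusted over the list alone), with a list median of −0.44 (camera adjusted p = 0.000102, 0.449 with estimated correlation). Amino acid synthesis was called with 0 called members (median 0.35, camera adjusted p = 1.09e-06, 0.643 with estimated correlation). So were ribosome biogenesis (median −0.15, camera adjusted p = 6.11e-05, 0.917 with estimated correlation) and mitochondrial respiration (median 0.25, camera adjusted p = 0.000492, 0.68 with estimated correlation). Fry called none of these 3 (adjusted p = 0.134, 0.575 and 0.186). The amino acid mean was 0.31 in place of 0.55 without cnb1Δ replicate 2 at 12 h, which stood apart in this list. The ribosome biogenesis call ended without WT replicate 2 at 12 h (camera adjusted p = 0.205, median −0.05), and its median was −0.10 without cnb1Δ replicate 2 at 0 h. In iron regulon genes 0 were above and 1 below, FIT1, of 16 (2 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.975). A simulated 2-fold difference between responses at 12 h was called in 64.2% of genes and a 1.5-fold difference in 11.9%, so smaller differences were seldom detectable. The count of 114 was 525 with the compared groups alone, 230 with DESeq2, and 235 and 239 with the replicate number as a block over all libraries and within strain. It fell to 66, 71 and 64 (30, 33 and 29 above) without replicate 1, 2 or 3 of WT at 0 h, 67 (26 above) without replicate 2 of WT at 12 h, and 68 and 68 (27 and 28 above) without replicate 1 or 3 of cnb1Δ at 0 h. Of 76 called without replicate 2 of cnb1Δ at 0 h, or 1 or 2 at 12 h, 40, 38 and 39 were above. Limma on TPM values put 37.6% to 38.0% of the calls above instead of 53.5%.

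**Figure D3:**
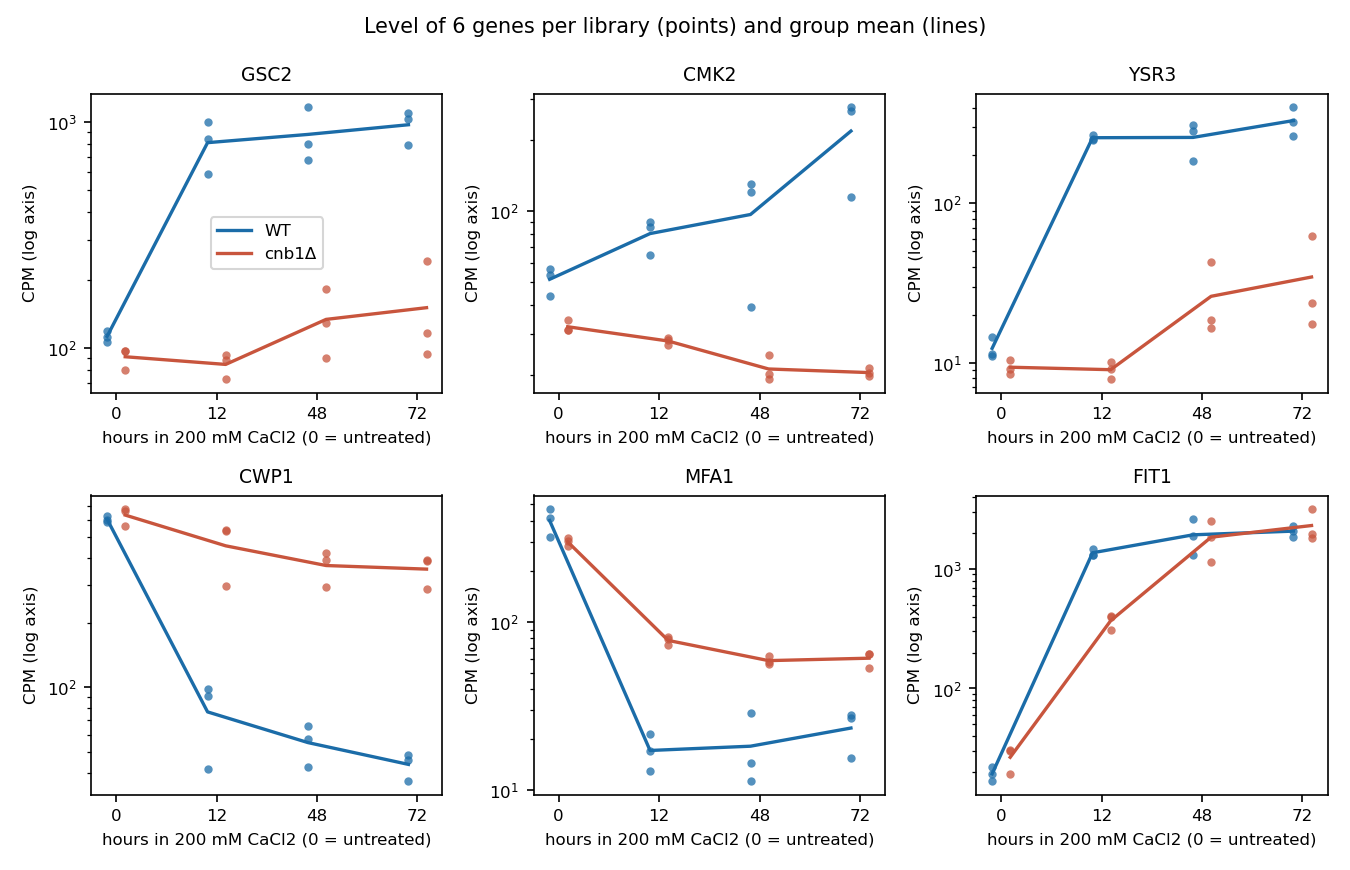
CPM on a log axis in each library for GSC2, CMK2, YSR3, CWP1, MFA1 and FIT1 at 0, 12, 48 and 72 h, with equal spacing between times. Points are libraries and lines join the group means of WT and cnb1Δ, and GSC2 at 12 h stands at 808 CPM in WT and 84.3 in cnb1Δ.

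At 48 h the responses of 12 genes differed, 7 above WT in cnb1Δ and 5 below, and 592 genes had an unadjusted p under 0.05. With the replicate number as a block within each time, which pairs the strains at 0 h and 48 h, 115 genes were called, 46.1% of them above WT. CWP1 (2.68 ± 0.37, edgeR adjusted p = 0.00332) and MFA2 (chromosome XIV, 352414 to 352530; 1.88 ± 0.31) were above, and GSC2 (−2.42 ± 0.42) and the stress gene HOR7 (−1.86 ± 0.30) were below. MFA1 (2.11 ± 0.36) and SST2, for a GTPase activator of the pheromone pathway (1.29 ± 0.22), were above too, but their calls ended without replicate 1 of cnb1Δ at 0 h (edgeR adjusted p = 0.0549 and 0.059), that of MFA1 also with the compared groups alone (0.082). Without that library 5 genes were called, 2 of them above. Without replicate 1 or 2 of WT at 48 h 20 genes were called each time (12 and 7 above), and 17 (5 above) without replicate 2 of cnb1Δ at 48 h. Of 8 called without replicate 2 of WT at 0 h or replicate 3 of WT or of cnb1Δ at 48 h, 3 were below each time. DESeq2 called 42 genes, the replicate block 30, or 39 within strain, and the fit without the late replicate 1 libraries 26. Among the lists, MATa-specific genes were above in 2 of 6 (6 and 0 adjusted over the list alone; median 1.29, camera adjusted p = 3.93e-10, 0.0682 with estimated correlation). Pheromone response genes were above in 1 of 14 (4 and 0 adjusted over the list alone; median 0.32, camera adjusted p = 0.000169, 0.335 with estimated correlation). That median was 0.18 without cnb1Δ replicate 1 at 0 h, 0.52 without its replicate 2 and 0.54 without WT replicate 2 at 48 h. Cell wall integrity genes were above in 3 of 17 (3 and 0 adjusted over the list alone; median 0.31, camera adjusted p = 1.36e-05, 0.307 with estimated correlation). Crz1 targets lay below, with 1 of 16 called (0 and 4 adjusted over the list alone; median −0.50, camera adjusted p = 2.21e-07, 0.259 with estimated correlation). Other settings put 40.0% (total count scaling), 42.9% (DESeq2), 43.3% (replicate number as a block) and 44.4% (limma on TPM values) of the calls above WT instead of 58.3%.

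At 72 h, 65 genes differed in response, 26 above WT in cnb1Δ and 39 below, and 20 of those below rose in WT and were not called in cnb1Δ. With the replicate number as a block within each time, which pairs the strains at 0 h and 72 h, 274 genes were called. CMK2 (−2.75 ± 0.46, edgeR adjusted p = 0.0043) went from 51.2 ± 6.89 to 219 ± 91.1 CPM in WT and from 32.2 ± 1.84 to 20.5 ± 0.776 CPM in cnb1Δ. MNC1 (chromosome II, 351255 to 351455; −3.87 ± 0.53), YSR3 (−2.87 ± 0.54), GSC2 (−2.39 ± 0.42), ICT1 (−2.09 ± 0.39) and the yapsin protease gene YPS3 (−1.95 ± 0.34) were below as well. CWP1 (2.96 ± 0.37), MFA2 (1.94 ± 0.31), RPI1 (1.64 ± 0.27) and SST2 (1.16 ± 0.22) were above. RTA1 was below (−4.01 ± 0.82), but its call ended without replicate 2 of WT at 0 h (edgeR adjusted p = 0.0651), any 1 of the 3 cnb1Δ libraries at 0 h (0.0564, 0.0727 and 0.0581) or replicate 2 of cnb1Δ at 72 h (0.0622). Among Crz1 targets 4 of 16 were below and 0 above (0 and 12 adjusted over the list alone), with a median of −0.96 (camera adjusted p = 1.77e-12, 0.113 with estimated correlation). MATa-specific genes were above in 3 of 6 (6 and 0 adjusted over the list alone; median 1.35, camera adjusted p = 1.57e-08, 0.0682 with estimated correlation). For pheromone response genes it was 1 of 14 (3 and 0 adjusted over the list alone; median 0.28, camera adjusted p = 0.00145, 0.43 with estimated correlation). Phosphate regulon genes were above in 1 of 15 (6 and 0 adjusted over the list alone; median 0.46, camera adjusted p = 1.04e-07, 0.386 with estimated correlation). Ergosterol genes were below in 2 of 23 (0 and 5 adjusted over the list alone; median −0.33, camera adjusted p = 3.41e-07, 0.46 with estimated correlation). For the catalytic subunit genes of calcineurin no difference in response was called at 72 h, with CNA1 at 0.29 ± 0.16 and CMP2 at 0.39 ± 0.17. The count of 65 was 140 with DESeq2, 122 with the replicate block, or 123 within strain, and 191 without the late replicate 1 libraries. It was 37 under total count scaling and 39 in limma on TPM values. It fell to 29 and 27 (9 and 8 above) without replicate 2 or 3 of WT at 0 h, 32 (13 above) without replicate 3 of WT at 72 h, and 30, 40 and 31 (7, 15 and 9 above) without replicate 1, 2 or 3 of cnb1Δ at 0 h. It was 25 and 33 (8 and 10 above) without replicate 2 or 3 of cnb1Δ at 72 h. Without replicate 1 of WT at 0 h or at 72 h 14 of 70 and 14 of 57 were above. Total count scaling put 29.7% of the calls above WT instead of 40.0%.

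**Figure D4:**
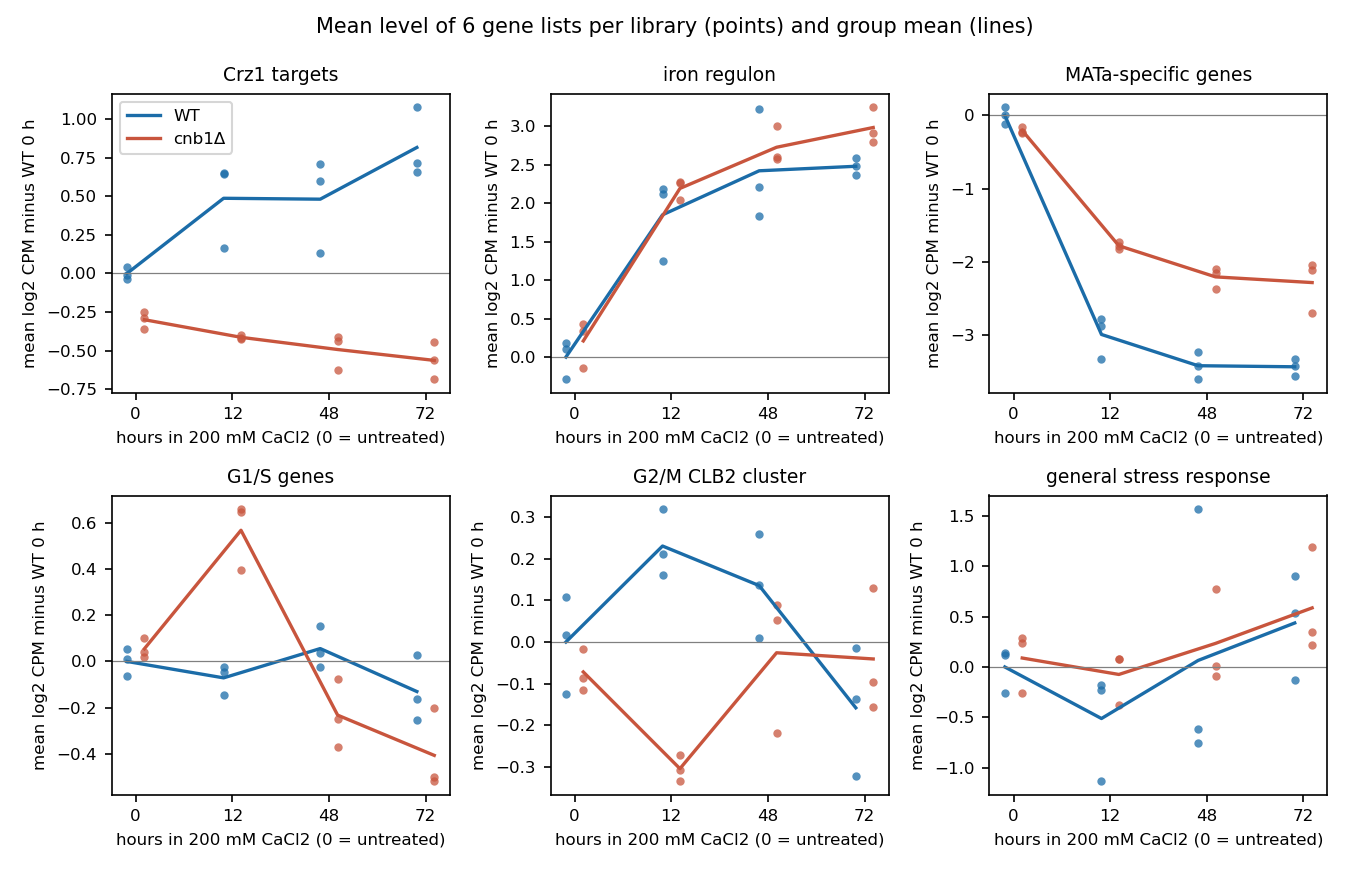
Mean log2 CPM of the genes of 6 lists in each library, minus the mean of WT at 0 h, at 0, 12, 48 and 72 h. Points are libraries and lines join the group means, and in Crz1 targets the cnb1Δ response at 72 h lies below that of WT by a median of −0.96 on the log2 scale.

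Principal component 3 parted the strains at 0 h. At 0 h edgeR called 2 genes, both lower in cnb1Δ, of 225 with an unadjusted p under 0.05. They were CNB1 (−7.31 ± 0.35, edgeR adjusted p = 3.59e-11) and the retrotransposon gene YDR210W-B (−4.72 ± 0.52, edgeR adjusted p = 6e-05, 4.38 CPM in WT against 0.157 in cnb1Δ), which was named after its values were seen. DESeq2 called 2 genes, limma on TPM values 1 in each of 3 settings, and edgeR 1 with a minimum mean of 10 CPM and 15 on these 6 libraries alone. Crz1 targets had 0 called members (0 and 2 adjusted over the list alone), and the list lay lower in cnb1Δ (median −0.32, camera adjusted p = 1.05e-05, 0.38 with estimated correlation). Cell wall integrity lay higher (median 0.11, camera adjusted p = 0.00218, 0.52 with estimated correlation). Fry called neither list (adjusted p = 0.109 and 0.239).

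At 12 h in CaCl2 527 genes were higher in cnb1Δ than in WT and 435 lower. YSR3 (−4.83 ± 0.42), PBI1 (−4.41 ± 0.63), HES1 (−4.20 ± 0.58), MNC1 (−3.52 ± 0.39) and GSC2 (−3.26 ± 0.32, edgeR adjusted p = 1.72e-06) were lowest. CWP1 (2.57 ± 0.27), TIS11, for an mRNA-binding protein of the iron response (2.52 ± 0.56), MFA1 (2.18 ± 0.27) and ARG1, for argininosuccinate synthetase (1.97 ± 0.36), were among the 5 highest. ARG1 was at 1.26 without cnb1Δ replicate 2 at 12 h. Also among them was HSP12 (2.85 ± 0.80), whose call ended without replicate 2 or 3 of WT at 12 h (edgeR adjusted p = 0.0782 and 0.0661). Crz1 targets were lower in 11 of 16 (0 and 11 adjusted over the list alone), with CMK2 at −1.52 ± 0.32 and the calcium and manganese pump gene PMR1 at −0.88 ± 0.12 (camera adjusted p = 4.15e-08, 0.209 with estimated correlation). PMR1 is overlapped by HUR1 on the other strand and the use of strand in counting is not given in the sources used here. Ergosterol genes were lower in 18 of 23 (0 and 20 adjusted over the list alone; camera adjusted p = 2.18e-16, 0.176 with estimated correlation), led by ERG28 (−1.65 ± 0.17) and ERG2 (−1.15 ± 0.17). Heat shock chaperones were higher in 11 of 15 (11 and 0 adjusted over the list alone; camera adjusted p = 3.47e-09, 0.184 with estimated correlation), with STI1 (1.45 ± 0.19) and BTN2 (1.32 ± 0.27). In G1/S genes 16 were higher and 1 lower (17 and 1 adjusted over the list alone) of 22 (camera adjusted p = 3.38e-11, 0.221 with estimated correlation), with CLB6 (1.34 ± 0.19) and SWI4 (1.35 ± 0.18). For the CLB2 cluster 0 were higher and 8 lower (0 and 10 adjusted over the list alone) of 12 (camera adjusted p = 1.13e-07, 0.357 with estimated correlation), with CLB1 (−1.04 ± 0.12) and CLB2 (−0.91 ± 0.15). Histone genes were lower in 4 of 8 (0 and 7 adjusted over the list alone; camera adjusted p = 9.13e-05, 0.43 with estimated correlation). Amino acid synthesis genes were higher in 10 of 29 (18 and 0 adjusted over the list alone; camera adjusted p = 5.33e-07, 0.625 with estimated correlation), and in 4 without cnb1Δ replicate 2 at 12 h, whose mean over the list, relative to WT at 0 h, was −0.02 against −0.61 and −0.58 in the other 2. The count of 962 fell to 622 without replicate 3 of WT at 12 h and to 555 without replicate 2 of cnb1Δ. Total count scaling put 72.6% of the calls higher, limma on TPM values 69.4% to 70.2%, and the main setting 54.8%.

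At 48 h 169 genes were higher in cnb1Δ and 137 lower, and with the replicate number as a block, which paired these libraries, 467 genes were called in place of 306, and 652 with the block within each time. MNC1 (−3.75 ± 0.39), RTA1 (−3.60 ± 0.50), YSR3 (−3.31 ± 0.39) and GSC2 (−2.72 ± 0.31) were lower and CWP1 (2.74 ± 0.27, edgeR adjusted p = 3.82e-06), MFA1 (1.69 ± 0.26) and ICY2 (1.67 ± 0.35) higher. Crz1 targets were lower in 11 of 16 (0 and 13 adjusted over the list alone; camera adjusted p = 7.2e-15, 0.0855 with estimated correlation), with CMK2 at −2.19 ± 0.33. A fit to these 6 libraries alone called 5 genes and ended the calls named here of every gene but CWP1 and KDX1 (adjusted p from 0.0597 for GSC2 to 0.171 for ICY2). Cell wall integrity genes were higher in 6 of 17 (11 and 1 adjusted over the list alone; camera adjusted p = 7.15e-09, 0.135 with estimated correlation), with KDX1 (1.47 ± 0.11) and PRM5 (1.47 ± 0.16). The count of 306 rose to 563 without replicate 1 of WT at 48 h and 524 without the late replicate 1 libraries, and fell to 162 without replicate 3 of WT, 128 without replicate 2 and 194 without replicate 3 of cnb1Δ. Replicate 1 of WT is the library with the highest general stress values.

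By 72 h 292 genes were higher in cnb1Δ and 278 lower, and 1038 genes were called in place of 570 with the replicate number as a block within each time. MNC1 (−4.98 ± 0.41), RTA1 (−4.42 ± 0.51), CMK2 (−3.42 ± 0.34, edgeR adjusted p = 2.3e-06) and YSR3 (−3.26 ± 0.39) were lowest, and CWP1 (3.03 ± 0.28), SPL2 (2.02 ± 0.42), ICY2 (2.01 ± 0.35) and PHO12 (1.81 ± 0.30) among the 5 highest. Of 16 Crz1 targets 13 were lower and 0 higher (0 and 16 adjusted over the list alone; median −1.29, camera adjusted p = 9.25e-18, 0.0682 with estimated correlation), with PHO89 (−2.60 ± 0.48) and NCW2 (−1.72 ± 0.18). In the calcium list RCN2, a regulator of calcineurin, was lower (−1.87 ± 0.34). In a fit to these 6 libraries alone, which called 182 genes, the calls of SPL2 (edgeR adjusted p = 0.072) and PHO89 (0.0703) ended. MATa-specific genes were higher in 6 of 6 (6 and 0 adjusted over the list alone; camera adjusted p = 4.13e-07, 0.103 with estimated correlation). Phosphate genes were higher in 8 of 15 (11 and 0 adjusted over the list alone; camera adjusted p = 4.82e-08, 0.374 with estimated correlation). The ergosterol genes were lower in 12 of 23 (0 and 15 adjusted over the list alone; camera adjusted p = 2.97e-11, 0.307 with estimated correlation). The count of 570 fell to 305 without replicate 3 of WT at 72 h and to 285 without replicate 2 of cnb1Δ, and limma on TPM values put 63.5% to 64.8% of the calls higher instead of 51.2%.

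From 12 h to 72 h in CaCl2, 764 genes rose and 687 fell in WT. PHO11 (−2.46 ± 0.41) and PHO12 (−2.28 ± 0.31, edgeR adjusted p = 0.000548), IMD2 (−3.24 ± 0.71), CIP1 (−2.18 ± 0.39) and GRX4, for a glutaredoxin (−1.78 ± 0.38, or −1.08 without WT replicate 2 at 12 h), fell furthest. HSP12 rose (3.41 ± 0.82), as did HSP26 (4.01 ± 1.21). The call of HSP26 ended without replicate 1 of WT at 72 h (2.65, edgeR adjusted p = 0.146), without replicate 1 (0.0795), 2 (0.0604) or 3 (0.0823) at 12 h and in limma on TPM values without a filter (0.0507). In the general stress list 9 rose and 1 fell (11 and 1 adjusted over the list alone) of 30 (camera adjusted p = 0.00489, 0.891 with estimated correlation). Without WT replicate 2 at 12 h 2 rose and 3 fell and the list call ended (camera adjusted p = 0.189), as it did by fry (0.248). Phosphate genes fell in 11 of 15 (0 and 12 adjusted over the list alone; camera adjusted p = 6.83e-07, 0.43 with estimated correlation). Ergosterol genes fell in 12 of 23 (0 and 15 adjusted over the list alone; camera adjusted p = 5.65e-07, 0.484 with estimated correlation). The count of 1451 fell to 635 and 543 without replicate 1 or 3 of WT at 12 h and to 495 and 736 without replicate 1 or 3 at 72 h. The compared groups alone gave 836, and total count scaling put 70.4% of the calls higher instead of 52.7%.

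In cnb1Δ over the same interval 625 genes rose and 642 fell. The G1/S list fell in 19 of 22 genes and rose in 0 (0 and 19 adjusted over the list alone; camera adjusted p = 9.26e-17, 0.135 with estimated correlation). It held YOX1 (−2.81 ± 0.30, edgeR adjusted p = 9.52e-06), CLB6 (−2.40 ± 0.20) and the G1 cyclin gene CLN2 (−2.29 ± 0.23). Histone genes rose in 6 of 8 (6 and 0 adjusted over the list alone; camera adjusted p = 0.000135, 0.444 with estimated correlation). IMD2 (−2.89 ± 0.68), FRE4 (−2.17 ± 0.36) and HO (−1.76 ± 0.15) fell and LSO1 rose (4.66 ± 0.92). The count of 1267 fell to 631 and 503 without replicate 1 or 3 of cnb1Δ at 12 h and to 572 without replicate 1 at 72 h, and 410 of 873 rose without its replicate 2. The change from 12 h to 72 h differed between the strains in 43 genes, 13 above WT in cnb1Δ and 30 below. HO (−1.75 ± 0.21, edgeR adjusted p = 0.000164) and the cyclin gene PCL1 (−1.69 ± 0.17) were below, and FIT1 (2.04 ± 0.38) and IRC8 (0.94 ± 0.15) above. The calls of FIT1 and IRC8 ended in limma on TPM values (adjusted p = 0.0762 to 0.102 and 0.115 to 0.129). Of 22 G1/S genes 10 were below and 0 above (0 and 17 adjusted over the list alone; median −0.88, camera adjusted p = 2.22e-31, 0.0682 with estimated correlation). Of 12 CLB2 cluster genes 5 were above and 0 below (9 and 0 adjusted over the list alone; median 0.73, camera adjusted p = 6.18e-17, 0.106 with estimated correlation). The count of 43 was 85 with DESeq2, 69 with the replicate block, or 77 within strain, and 84 without the late replicate 1 libraries. It was 17 under total count scaling, 20 with the compared groups alone and 7 in limma on TPM values, which put 14.3% of the calls above WT instead of 30.2%. Without replicate 1, 2 or 3 it was 18, 34 and 19 (3, 6 and 4 above) for WT at 12 h and 23, 28 and 33 (5, 8 and 4 above) at 72 h. For cnb1Δ it was 15, 26 and 26 (2, 3 and 8 above) at 12 h and 44, 20 and 23 (5, 6 and 7 above) at 72 h.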

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

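The results in this part were singled out because a test of the difference between the responses of cnb1Δ and WT passed its threshold, for a gene with edgeR and for a gene list with both camera and fry. Of the tests below, those on length and GC content and that on diploid cells were set before their result was seen, and all others, the counts over other splits included, were chosen after it.

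The responses of 114 genes differed at 12 h, 12 at 48 h, 65 at 72 h, and 43 in the change from 12 h to 72 h. When strain labels were exchanged among the same libraries, 10 of 100 splits at 12 h gave as many (highest other 559) and 14 of 100 at 48 h (263). At 72 h 15 of 100 did (161) and 11 of 100 for the change from 12 h to 72 h (1523), so chance cannot be excluded by these shares. Of the other splits that gave as many, all 9 at 12 h, 11 of 13 at 48 h and all 14 at 72 h kept the strain labels of that time. Of 10 for the change from 12 h to 72 h, 3 kept them together at 72 h and 7 at 12 h alone. Splits that mixed strains at both times gave at most 3, 86, 0 and 1. These fits had no block. Where the numbers pair the strains at both times, 16 of the other splits at 48 h and 15 at 72 h part all pairs as the real one does. Of each, 5 gave as many, all with the later time's strain labels kept. Those of them that mixed the strains at both times (9 and 7) gave 0. For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split alone gave as many in all of these but cnb1Δ against WT at 48 h. The highest other was 0 for the changes from 0 h, for the strains at 0 h and 12 h and for 72 h against 12 h in cnb1Δ, 1 for 72 h against 12 h in WT and 3 for the strains at 72 h. At 48 h 2 of 10 splits gave at least 306 genes, the other with 1403, which points to a structure of the samples. It set WT replicate 1 and cnb1Δ replicates 1 and 2 against the other 3 libraries and parts 1 pair of equal numbers, where the real split parts 3.

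At 12 h the differences were FUS1 2.86 (1.59 in limma on log2(TPM + 1)), MFA1 2.60, CWP1 2.51, NFG1 2.09, MDG1 1.70, BAR1 1.65, HO 1.59, PHD1 1.52, MFA2 1.46 and CAR1 1.37 above WT (log2). YSR3 −4.44, PBI1 −4.40, HES1 −4.27, FHN1 −3.25, YHK8 −3.21, GSC2 −2.96, MNC1 −2.41, FIT1 −2.35, IZH4 −2.31 and SCM4 −1.89 lay below. Leaving out 1 library ended the calls of BAR1 for 11 of the 12 libraries (edgeR adjusted p = 0.0558 to 0.116) and NFG1 for 10 (0.0509 to 0.106). It did so for MFA2 without WT replicate 2 at 12 h (0.0565) or cnb1Δ replicate 2 at 0 h (0.0506). It did for MNC1 without replicate 2 of WT at 0 h (0.0566) or of cnb1Δ at 0 h (0.0504) or 12 h (0.0541), and for PHD1 without WT replicate 2 at 12 h (0.0534) or cnb1Δ replicate 1 at 0 h (0.05). SCM4 lost its call without WT replicate 1 (0.0541) or 3 (0.0617) at 0 h, WT replicate 2 at 12 h (0.0652) or cnb1Δ replicate 2 at 0 h (0.0609).

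At 48 h they were CWP1 2.68, MFA1 2.11, MFA2 1.88, SST2 1.29 and PRM5 1.09 above, and YSR3 −2.92, MNC1 −2.63, GSC2 −2.42 and HOR7 −1.86 below. The calls of MNC1 and PRM5 ended without most of the single libraries (edgeR adjusted p up to 0.121 and 0.163). YSR3 lost its call without WT replicate 1 (0.0506) or 2 (0.079) at 0 h, WT replicate 3 at 48 h (0.0588), cnb1Δ replicate 1 at 0 h (0.059) or cnb1Δ replicate 3 at 48 h (0.0642). MFA1 and SST2 lost theirs without cnb1Δ replicate 1 at 0 h (0.0549 and 0.059).

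At 72 h they were CWP1 2.96, PHM6 2.07, MFA2 1.94, MFA1 1.80, RPI1 1.64, PHD1 1.41, SST2 1.16, AGA2 1.07, CAR1 1.06 and KDX1 0.90 above. Those below were RTA1 −4.01, MNC1 −3.87, YSR3 −2.87, CMK2 −2.75, FHN1 −2.70, GSC2 −2.39, RCR1 −2.36, ICT1 −2.09, DIA1 −2.08 and YPS3 −1.95. DIA1 is overlapped on the other strand by YMR316C-A. The calls of PHM6, PHD1, AGA2, CAR1, FHN1 and RCR1 ended without most of the single libraries (edgeR adjusted p up to 0.074, 0.116, 0.141, 0.141, 0.105 and 0.133). That of DIA1 ended without WT replicate 2 at 0 h (0.0647) or 3 at 72 h (0.0592) and that of MFA1 without WT replicate 3 (0.0587) or cnb1Δ replicate 1 (0.0537) at 0 h or cnb1Δ replicate 2 at 72 h (0.0505). RTA1 lost its call as given for the responses at 72 h (up to 0.0727), and KDX1 under total count scaling (0.057) and limma on TPM values (0.064 to 0.0748). Between 12 h and 72 h the differences were FIT1 2.04, PLB2 1.20, CLB2 1.01, IRC8 0.94 and CHS2 0.90 above, and HO −1.75, PCL1 −1.69, CLN2 −1.52, MET14 −1.44 and KCC4 −1.40 below. PLB2, CLB2, CHS2, CLN2, MET14 and KCC4 lost their calls without most of the single libraries (up to 0.13, 0.0914, 0.0817, 0.087, 0.087 and 0.109), and limma on TPM values ended those of FIT1 (0.0762 to 0.102) and IRC8 (0.115 to 0.129).

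Among lists the medians at 12 h were Crz1 targets −0.44, heat shock chaperones 0.62, G1/S 0.53, the CLB2 cluster −0.51, ergosterol synthesis −0.68, pheromone response 0.38 (0.60 without cnb1Δ replicate 2 at 0 h) and MATa-specific genes 1.30. At 48 h they were Crz1 targets −0.50, cell wall integrity 0.31, pheromone response 0.32 (0.18 to 0.54 leaving out 1 library) and MATa-specific genes 1.29. At 72 h they were Crz1 targets −0.96, the phosphate regulon 0.46, ergosterol synthesis −0.33, pheromone response 0.28 and MATa-specific genes 1.35, and between 12 h and 72 h G1/S −0.88 and the CLB2 cluster 0.73.

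The replicate 1 libraries of 48 h and 72 h deviated from their groups together in both strains. Length or GC bias is argued against in genes where both are known. The mean correlation over the 6 pairs was 0.726 after regression (0.677 to 0.828) and 0.723 before. A library batch shared by every replicate 1 library is argued against by a mean correlation of 0.0232 between late and early ones (16 pairs, all genes, −0.273 to 0.215). A slower-growing or stressed state of these cultures cannot be told apart from other causes: 3 of 4 libraries stood above both others of their group in general stress genes and below both in ribosome biogenesis genes (0.16 against 0.75 in WT and 0.48 against 0.59 in cnb1Δ at 48 h, 0.54 against 0.55 in WT and 0.30 against 0.49 in cnb1Δ at 72 h). A batch or culture history shared by the late replicate 1 samples alone is not given in the labels and stays open.

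At 12 h G1/S genes lay above and CLB2 cluster genes below the WT response in cnb1Δ. A factor per library moves both list medians alike, so their gap of 1.03 (0.99 to 1.10 leaving out 1 library) does not test scaling. Length or GC bias is argued against, since they were 1.03 apart after regression (0.98 to 1.08 leaving out 1 library). A candidate explanation, that fewer cells were past G1/S in cnb1Δ, stays open. The histone list, median −0.35, was called by camera but not with an estimated correlation (adjusted p = 0.543) or by fry (0.0572). S phase genes linked to Hcm1 were not lower in cnb1Δ at 12 h (mean over WT at 0 h 0.40 to 0.48, WT 0.23 to 0.54). The G1/S and CLB2 calls were lost with an estimated correlation (adjusted p = 0.213 and 0.386).

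MATa-specific genes fell in CaCl2 in both strains. MATalpha cells in the treated cultures are argued against by MATalpha-specific genes, whose highest median over the 3 times in WT was −1.25, from 2 measured genes, STE3 and SAG1. Diploid cells, in which haploid-specific genes are off, are argued against by STE4 and STE18, whose mean fell by 0.753% of the fall of the MATa-specific genes at 12 h and lay above 0 at 48 h and 72 h, at 0.10 and 0.21 (STE4 0.17, 0.31 and 0.37 and STE18 −0.21, −0.10 and 0.04 at 12, 48 and 72 h in WT, SE 0.09 and 0.16). At least 91.7% of the median fall was left under RLE or total count scaling. Under the latter it was −2.74, −3.26 and −3.43 at 12, 48 and 72 h in WT. These scalings differ too little to test scaling as a cause. No biological explanation of the fall was tested, time in culture without CaCl2 was not sampled, and the difference between the strains stays open.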

How the results depend on the processing

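The alternative without the replicate 1 libraries of the 48 h and 72 h groups, the replicate block within time and leaving out 1 library in list tests were chosen after the data were examined, and all others before. The counts of the changes from 0 h stayed within 1.5 times the main count under every alternative. Leaving out 1 library gave 2339 to 2861 (WT 12 h), 3547 to 3995 (48 h), 3647 to 3883 (72 h), 1960 to 2225 (cnb1Δ 12 h), 2962 to 3251 (48 h) and 3270 to 3611 (72 h). The other counts moved, and the cause was not tested except where fewer libraries were fitted. For the interactions at 12, 48 and 72 h and between 12 h and 72 h (114, 12, 65 and 43) DESeq2 gave 230, 42, 140 and 85, the replicate block 235, 30, 122 and 69, and the replicate block within strain 239, 39, 123 and 77. The fit of the compared groups alone gave 525 at 12 h and 20 between 12 h and 72 h, and total count scaling 37 at 72 h and 17 between 12 h and 72 h. Limma on TPM values gave 39 in each of 3 settings at 72 h and 7 in each between 12 h and 72 h. Without the late replicate 1 libraries there were 26, 191 and 84 at 48 h, 72 h and between 12 h and 72 h. Leaving out 1 library gave 64 to 100, 5 to 20, 25 to 75 and 15 to 44, and the libraries that moved these counts over 1.5-fold are named in the report with their values.

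Between the strains at 0 h (2 genes), a mean of at least 10 CPM gave 1, limma on TPM values 1, 1 and 1, the compared groups alone 15, and leaving out 1 library 2 each time. At 12 h (962) leaving out 1 library gave 555 to 751. At 48 h (306) the compared groups alone gave 5, the replicate block 467, the setting without late replicate 1 libraries 524, and leaving out 1 library 128 to 563. At 72 h (570) the compared groups alone gave 182 and leaving out 1 library 285 to 495. From 12 h to 72 h in WT (1451) the compared groups alone gave 836 and leaving out 1 library 495 to 1665, and in cnb1Δ (1267) leaving out 1 library gave 503 to 1142. The correlation of the strains' responses (0.776, 0.858 and 0.834) was 0.625, 0.706 and 0.702 with no filter, and 0.674, 0.748 and 0.736 with DESeq2. It was 0.928 at 48 h and 0.910 at 72 h for genes with at least 10 CPM, and 0.746 to 0.778, 0.805 to 0.866 and 0.780 to 0.854 leaving out 1 library.

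Of 544 list tests 188 were called, and 0 with an estimated correlation (lowest adjusted p = 0.0682). Fry called 169, 124 of them among the 188, RLE size factors 187 (187), total count scaling 197 (177), the replicate block 198 (184), and without late replicate 1 libraries 143 of 374 were called (119 of 131). Of 271 named gene results 211 kept their side and direction under every alternative, 60 lost their call under at least 1 (45 leaving out 1 library, 41 in another planned setting) and 0 reversed. The ribosomal protein list in the interaction at 48 h turned direction without the late replicate 1 libraries (camera adjusted p = 0.577) and without WT replicate 1 at 48 h (0.0445, and 1.15e-08 to 0.439 over all left-out libraries). Without cnb1Δ replicate 1 at 72 h so did its tests between the strains at 72 h (0.637, the highest of a range from 1.59e-09) and from 12 h to 72 h in cnb1Δ (0.84, from 6.17e-07). Leaving out 1 library gave 178 to 207 called lists. Of the 188, 46 lost their call or turned without at least 1 library, the median of 60 moved over 1.5 times and so did the called members of 63. The replicate block within time, which pairs the strains at 0, 48 and 72 h, gave 115 and 274 genes for the interactions at 48 h and 72 h and 2, 652 and 1038 between the strains at 0, 48 and 72 h. Of 170 list tests it called 62 (56 of 60). It ended no call of a named gene. Over all libraries the block is no paired result where numbers do not pair the libraries, which correlated by −0.273 to 0.695 over all 84 pairs of equal number. Where they do, it changed the count at 48 h between the strains and the list calls given beside their values. Neither block changed another call named here.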

Other observations

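Further lists, fixed before the data were examined, are described here. The tests of lists without single libraries were chosen afterwards. M/G1 daughter genes, expressed as daughter cells leave mitosis, were higher in cnb1Δ than in WT at 48 h in 4 of 12 (8 and 0 adjusted over the list alone; median 0.44, camera adjusted p = 1.47e-06, 0.404 with estimated correlation). Without WT replicate 1 at 48 h, the library apart from its group, the median was 0.26 and the call stayed (camera adjusted p = 0.00785). At 72 h they were higher in 5 (8 and 0 adjusted over the list alone; camera adjusted p = 2.23e-05, 0.46 with estimated correlation). The unfolded protein response list was lower in cnb1Δ at 48 h, with 1 of 15 called (0 and 5 adjusted over the list alone; median −0.21, or −0.14 without WT replicate 2 at 48 h; camera adjusted p = 0.000102, 0.184 with estimated correlation). Translation factors fell from 12 h to 72 h in WT in 5 of 25 (0 and 7 adjusted over the list alone; median −0.21, or −0.14 without WT replicate 3 at 72 h; camera adjusted p = 0.000607, 0.776 with estimated correlation), and were not called by fry (adjusted p = 0.136). Hexose transporters rose over the same interval in cnb1Δ in 4 of 9 (7 and 0 adjusted over the list alone; median 0.96, camera adjusted p = 0.00927, 0.652 with estimated correlation). Without cnb1Δ replicate 1 at 72 h 2 of them rose and the mean was 0.62 in place of 1.08, with the list still called (camera adjusted p = 0.0379), and without cnb1Δ replicate 2 at 12 h the list call ended (0.0554). The vacuolar H+-ATPase list, a proton pump, was lower in cnb1Δ at 12 h, with 1 of 14 called (0 and 0 adjusted over the list alone; median −0.22, or −0.15 without WT replicate 3 at 12 h; camera adjusted p = 0.00582, 0.57 with estimated correlation).

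The following lists were not called for WT at 12 h against 0 h. In the proteasome 10 rose and 10 fell (11 and 10 adjusted over the list alone) of 33 (camera adjusted p = 0.88). Among signs of other cell types and states, 2 rose and 3 fell (2 and 3 adjusted over the list alone) of 11 meiosis genes (camera adjusted p = 0.7). Likewise 1 rose and 0 fell (0 and 0 adjusted over the list alone) of 8 stationary phase genes (camera adjusted p = 0.82), and 0 rose and 2 fell (0 and 2 adjusted over the list alone) of 2 MATalpha-specific genes (camera adjusted p = 0.197).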
